A study of Mus musculus with 90 samples.

How the data were processed

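Primary skeletal-muscle myoblasts of Balb/c mice were grown in a serum-rich medium with basic fibroblast growth factor and then moved to a high-glucose medium with little horse serum, per the labels' protocols. Cells were taken at 0, 6, 12, 18, 24, 36 and 48 h and at 3, 4 and 7 days after the change of medium (10 times). Each time was measured in 3 named cultures, mb1, wtp16 and wt841, which gives 30 RNA samples. Each was hybridized to 3 Affymetrix arrays of the mouse U74 version 2 set, A, B and C, for 90 arrays. The series title calls the cultures MyoD wild type. Whether the 3 names stand for 3 animals, 3 isolations or 3 lines is not given in the sources used. In tests over time each culture was therefore 1 replicate. The p-values rest on how differently these 3 cultures change, pooled over all 10 times. Unless another n is given, n = 3 per time. The tests of culture and culture by phase use times as replicates. The fits take times as independent, although those of a culture are 1 series.

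The values used are the deposited signal intensities, MAS5 signals per the submitters' processing notes, which give no version of that program. Their mean after leaving out 2% of the probe sets at each end lay between 1499.6 and 1499.7 on all 90 arrays, so the arrays had been brought to a common level before deposition and were used as deposited, without a further scaling. Detection calls and raw image data were not used here. A pseudocount, the 20th percentile of all signals of an array type (79.9 for A, 190.5 for B and 184.5 for C), was added before taking log2. Signal levels in the text are mean ± SD of the deposited intensities, and changes are log2 differences of the values with the pseudocount. Array medians ran from 405.6 to 557.4 on A, 715.1 to 907.2 on B and 520.8 to 858.8 on C. No 2 arrays held the same values, with r between 0.795 and 0.985 for pairs of A arrays, 0.66 and 0.971 for B and 0.627 and 0.941 for C.

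After 198 control probe sets were left out, 36701 remained (12422 on A, 12411 on B and 11868 on C). In the platform annotation 29131 of them carry 1 gene, 724 several and 6846 none, and together they stand for 15964 genes. The gene identifiers of 29044 probe sets were found in the reference gene table, and 0 symbols had to be replaced, a plain lookup without a test or p-value. Every probe set was tested. For gene names and gene lists only probe sets with exactly 1 gene were used, and a gene was represented by its brightest probe set, with plain probe sets preferred to those whose suffix marks possible cross-hybridization. Chromosomal positions were not used here.

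Each probe set was fitted with limma 3.58.1 in R 4.3.3, with time as the factor and culture as a block, separately for each array type, followed by moderated statistics. The p-values of the 3 array types were adjusted together by the Benjamini-Hochberg method over all 36701 probe sets, and an adjusted p under 0.05 was called a change. The SE of a change is the moderated one. Tested were each later time against 0 h, 7 days against 48 h, the time course as a whole (an F test over the 10 times) and the culture difference as a whole (an F test over the 3 cultures). All of these choices, the gene lists and the rule for naming genes were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

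A set of 30 gene lists was written from general knowledge of muscle and tested with camera, at its preset inter-gene correlation of 0.01, for 6 h, 24 h and 7 days against 0 h and for 7 days against 48 h. The 120 p-values were adjusted together. Of the lists, 23 describe programs and 7 hold markers of cells other than muscle. The same tests were repeated with a correlation estimated from each list's own residuals, and the adjusted p stands second. For each list the text gives its measured members, those risen, fallen and not called over all probe sets, and the number called when p-values were adjusted over the list alone.

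Genes were named by a rule. At 6 h, 24 h and 7 days the 10 largest rises and 10 largest falls were eligible, and at 7 days against 48 h the 5 largest each way, among genes past the threshold that moved the same way in all 3 cultures. To these were added the 10 genes with the largest range between cultures, up to 4 called members of each list with the largest change, and a fixed set: Pax7, Myf5, Myod1, Myog, Myf6, Mef2a, Mef2c, Mef2d, Cdkn1a, Ccnd1, Mki67, Myh3, Acta1 and Ckm. Names that are only clone or expressed-sequence labels were passed over, 1 among the falls at 6 h and 1 among the falls at 24 h. Only 8 falls at 6 h and 1 fall at 7 days against 48 h met the rule. Pax7 has no probe set that carries it alone. Genes outside the rule are named as such.

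The pipeline was tried on simulated values, 36701 probe sets at the same times and cultures. Of 100 probe sets given a log2 change of 1 at 24 h, 15 were recovered. Of 100 given 2, 61 were, with median estimates of 1 and 1.97. Among 81 calls 5 were false, and 0 probe sets were called at 7 days, where nothing changed. A list shifted by 0.5 log2 had a camera p of 8.449e-12, and 3 of 100 random lists an unadjusted p under 0.05. With this few changes a 2-fold change was mostly missed. The real share of changes and correlated lists were not simulated, so real lists are not covered.

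Samples were checked for the pairing that the culture block assumes. After the mean of each time was taken away, arrays of the same culture correlated with a median r of 0.46 on A, 0.39 on B and 0.29 on C, and arrays of different cultures with −0.27, −0.25 and −0.25. Of 135 same-culture pairs per array type, r exceeded 0.1 in 128, 126 and 126. The lowest values, −0.21, −0.14 and −0.14, all involve the wt841 sample of 7 days, without which the lowest are 0.19, 0.21 and 0.17. Per the scan records in the array headers, each culture was scanned as its own batch, mb1 with another scanner model than the other cultures, but the wt841 sample of 7 days was scanned with wtp16 on every array type. On type B, the mb1 and the wt841 arrays of 4 days were each scanned alone on a day of their own, and the wtp16 array of 36 h has no scan record. These 3 arrays were counted with the batch of their culture. Culture and scan batch are thus almost the same variable, and changes over time within a culture are differences within a scan batch except for that sample and, as far as known, those 3 arrays. The ratio of 3' to 5' signal ran from 0.75 to 0.89 for Gapdh and from 0.53 to 1.16 for Actb over the samples.

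Signals of 3' arrays show amounts of RNA relative to the rest of the same sample, not protein, cell fusion or cell number, and a fall in a cycling gene does not tell how many cells stopped dividing. The number of arrays limits the precision of every estimate.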

Results

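Myoblasts that are moved from growth medium to differentiation medium leave the cell cycle, switch on muscle genes and fuse into myotubes. When each part of that program begins in primary mouse myoblasts, and how alike 3 separately named cultures are in it, was read from 10 times between 0 h and 7 days. Of the fixed genes, Ccnd1, which encodes cyclin D1 of the G1 phase, was called first, at 6 h, on 1 of its 3 probe sets. Its other probe sets were not called at 6 h (−1.94, adjusted p = 0.0861, and −1.75, adjusted p = 0.0749). The call of Ccnd1 also ended without mb1 of 0 h (−2.16, adjusted p = 0.0981), wtp16 of 0 h (−1.89, adjusted p = 0.348), mb1 of 6 h (−2.28, adjusted p = 0.056), wtp16 of 6 h (−2.22, adjusted p = 0.219) or wt841 of 6 h (−2.51, adjusted p = 0.0971). Myog, Mef2a and Myh3 followed at 12 h, and Myf6, Mef2c, Mef2d, Cdkn1a, Mki67 and Acta1 at 18 h. This order turns with 1 sample, since without wt841 of 0 h Myog (2.37), Mef2a (1.39), Mef2c (2.68), Myh3 (3.01) and Acta1 (2.60) were called at 6 h as well, with adjusted p from 0.00853 to 0.0377. Myod1 fell at 3 days. Myog, the transcription factor that starts terminal differentiation, had its largest change at 18 h (log2 change 2.55), Myh3 at 36 h (4.31) and Myf6 at 7 days (3.33). Myf5 (adjusted p = 0.0556), Cdkn1a (adjusted p = 0.112) and Ckm (adjusted p = 0.886) did not pass the test of the whole course on the probe sets that represent them. Of the other probe sets of Ckm 2 passed it (adjusted p = 5.31e-05 and adjusted p = 9.14e-05).

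The number of probe sets that differed from 0 h grew from 44 of 36701 at 6 h to 557 at 12 h, 2037 at 18 h and 2333 at 24 h (limma adjusted p under 0.05, n = 3 per time). It was 2913 at 36 h, 3341 at 48 h, 3983 at 3 days, 4202 at 4 days and 4802 at 7 days. Over the course as a whole 3382 probe sets changed (9.2%). Without the wtp16 sample of 0 h the counts were 55 at 12 h, 723 at 18 h, 1527 at 36 h, 1857 at 48 h, 2341 at 3 days and 2633 at 4 days. Other single samples moved the count at 12 h to 1004 (wt841 of 0 h left out), 289 (mb1 of 0 h), 172 (mb1 of 12 h), 346 (wtp16 of 12 h) and 125 (wt841 of 12 h). They moved that at 18 h to 1254 (mb1 of 18 h) and 913 (wtp16 of 18 h), that at 36 h to 1799 (wtp16 of 36 h) and that at 48 h to 2151 (wtp16 of 48 h). Without the culture block 59, 653, 1170, 1370, 1706 and 1928 probe sets were called at 12 h, 18 h, 36 h, 48 h, 3 days and 4 days, and 1096 over the course. A pseudocount of 1 left 305 at 12 h. The count over the course was 245 without mb1, 529 without wtp16 and 2068 without wt841. Fits of only 6 samples called 0 probe sets at 12 h, 18 h and 36 h (limma, with 3824, 4857 and 5603 at an unadjusted p under 0.05). At 48 h, 3 days and 4 days such fits called 193, 287 and 341.

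**Figure D1:**
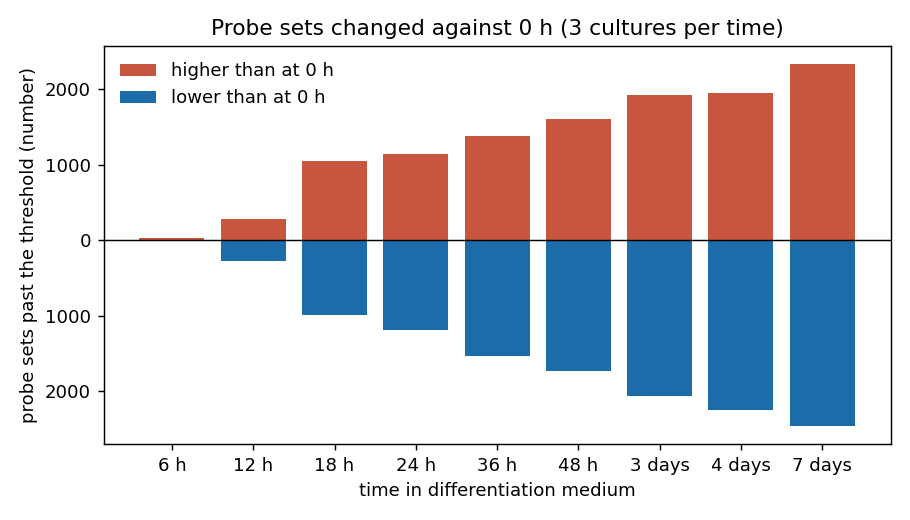
Probe sets higher and lower than at 0 h at each later time (limma, adjusted p under 0.05, n = 3 cultures per time).

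**Figure D2:**
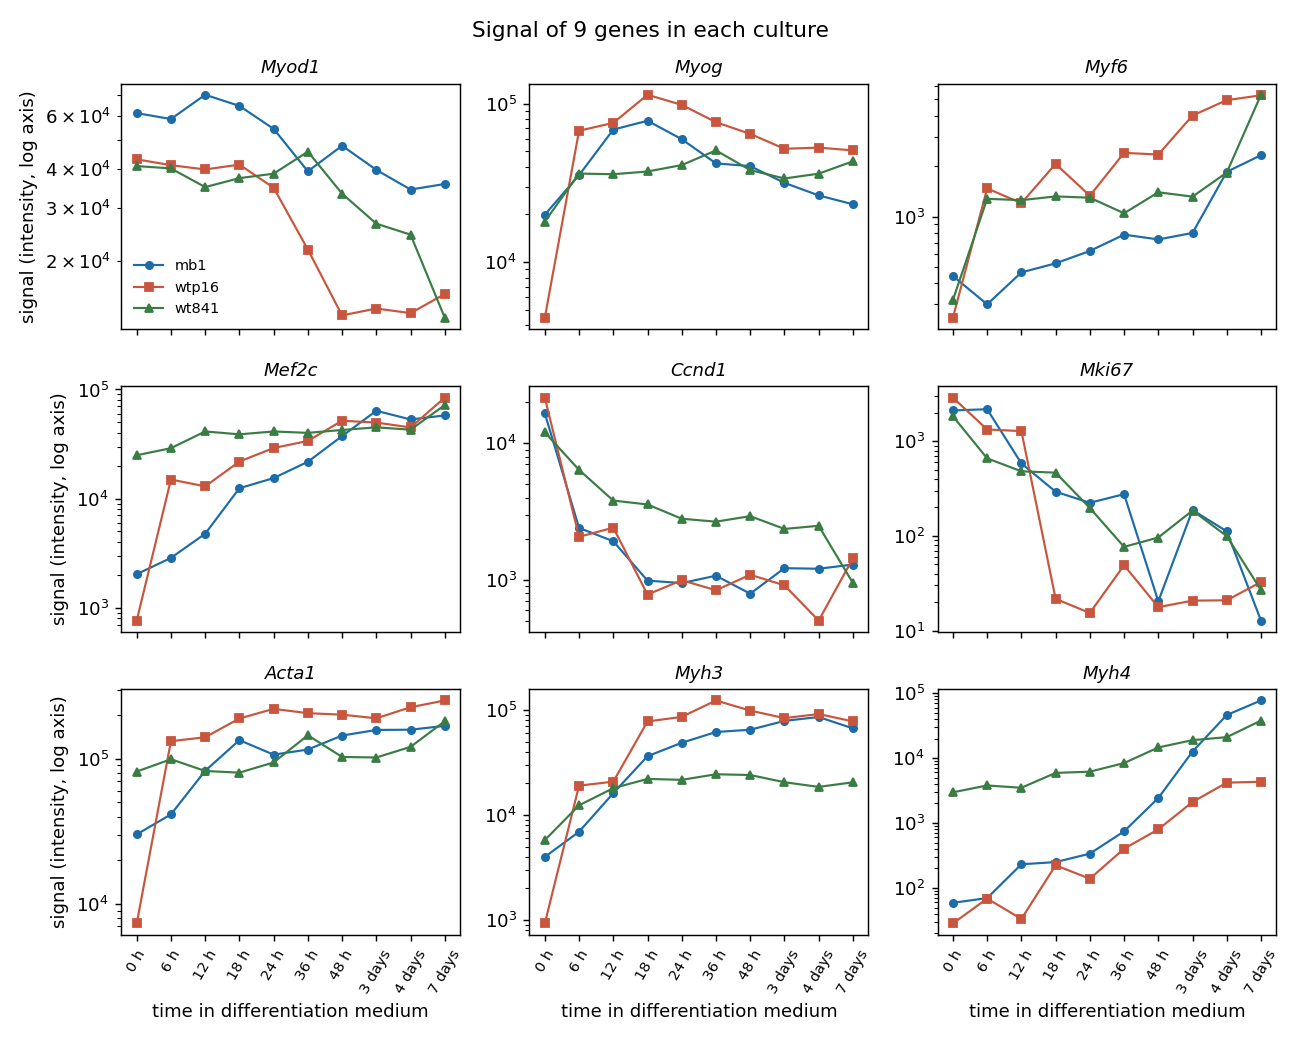
Signal of 9 genes of the myoblast and muscle program at the 10 times, 1 line per culture (log scale, n = 1 per culture and time).

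What differs within 6 h of the change of medium was asked with the 6 h samples against 0 h, where 28 probe sets were higher and 16 lower. That balance turned to 15 higher and 36 lower without mb1 of 0 h, 2 and 3 without wtp16 of 0 h, and 45 and 57 with the higher pseudocount. The largest rise was that of Klhl40 (log2 change 2.46 ± 0.40 SE, adjusted p = 0.00874, n = 3), which encodes a kelch protein of the thin filament, with a mean signal of 21520 ± 13410 against 3379 ± 1746. The next rises were those of Ppfia4 (2.15), Pdlim3 (2.07), Maf (2.04), Fibin (1.77) and Slc40a1 (1.74), with adjusted p from 0.00497 to 0.0283. Pdlim3 is a protein of the Z-disc, Maf a transcription factor and Slc40a1 the iron exporter, and the probe set of Fibin carries a suffix for possible cross-hybridization. They were followed by Msmo1 (1.65), Rbm24 (1.65), Narf (1.57) and Tpd52l1 (1.47), with adjusted p from 0.0187 to 0.0283. Msmo1 is an enzyme of sterol synthesis and Rbm24 an RNA-binding protein of muscle.

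The largest falls at 6 h were those of Hmga2 (log2 change −2.87 ± 0.47 SE, adjusted p = 0.0134, n = 3), a chromatin protein of proliferating cells, and Ccnd1 (log2 change −2.33 ± 0.43 SE, adjusted p = 0.0283, n = 3). Their mean signals were 1506 ± 869 against 12030 ± 8566 and 3614 ± 2405 against 16770 ± 4814. Falls were also called for Zfp36l2 (−2.31), Errfi1 (−1.78) and Pdpn (−1.57), with adjusted p from 0.0041 to 0.0199, of which Errfi1 is a feedback inhibitor of the EGF receptor. Smaller falls were those of Rai14 (−1.29), Dok1 (−1.08) and H2ax (−0.90), with adjusted p from 0.0283 to 0.0469.

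With all samples the muscle genes of the fixed set were not yet called at 6 h, unlike Klhl40, Pdlim3 and Rbm24 above. The log2 changes of these fixed genes were Myog (1.91), Myh3 (2.04), Acta1 (1.63), Mef2c (1.55), Myf6 (1.18) and Mef2a (1.01), with adjusted p from 0.111 to 0.496. Without wt841 of 0 h Myog (2.37), Myh3 (3.01), Acta1 (2.60), Mef2c (2.68) and Mef2a (1.39) were called, with adjusted p from 0.00853 to 0.0377, and without mb1 of 0 h Myog (2.40) and Myf6 (1.77), with adjusted p from 0.0439 to 0.0492. The other fixed genes had values of Cdkn1a (0.97), Myf5 (0.91), Mef2d (0.64), Ckm (−0.01), Myod1 (−0.05) and Mki67 (−0.80), with adjusted p from 0.331 to 0.998. Myog stood at 0.83 in mb1, 3.89 in wtp16 and 1 in wt841.

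As groups, 7 of the 30 lists rose and 5 fell at 6 h. The sarcomere list rose (median 1.29, camera adjusted p = 3.66e-16, 0.143 with estimated correlation). Among its 42 members 1 rose, 0 fell and 41 were not called, with 25 risen and 0 fallen over the list alone. Its medians were 0.28 in mb1, 2.63 in wtp16 and 0.70 in wt841. Excitation-contraction coupling and calcium handling rose (median 0.94, camera adjusted p = 2.89e-08, 0.143 with estimated correlation). Of 22 members 0 were called by limma, with 14 higher and 0 lower at an unadjusted p under 0.05, and 13 risen and 0 fallen over the list alone. Muscle energy metabolism rose (median 0.64, camera adjusted p = 1.74e-06, 0.242 with estimated correlation). Of 28 members 0 were called by limma, with 11 higher and 1 lower at an unadjusted p under 0.05, and 6 risen and 1 fallen over the list alone. Differentiation regulators rose (median 0.73, camera adjusted p = 8.27e-07, 0.0808 with estimated correlation). Of 22 members 0 were called by limma, with 14 higher and 0 lower at an unadjusted p under 0.05, and 7 risen and 0 fallen over the list alone. Neuromuscular junction genes rose (median 0.31, camera adjusted p = 0.00455, 0.137 with estimated correlation). Of 18 members 0 were called by limma, with 5 higher and 0 lower at an unadjusted p under 0.05, and 4 risen and 0 fallen over the list alone. Mitochondrial respiration rose (median 0.21, camera adjusted p = 0.000101, 0.369 with estimated correlation). Of 34 members 0 were called by limma, with 4 higher and 0 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone. Cholesterol synthesis rose (median 0.30, camera adjusted p = 0.000335, 0.2 with estimated correlation). Among its 20 members 1 rose, 0 fell and 19 were not called, with 4 risen and 0 fallen over the list alone. The cholesterol medians were 1.17 in mb1, −0.08 in wtp16 and 0.18 in wt841.

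The falling groups at 6 h were led by DNA replication and G1/S (median −0.74, camera adjusted p = 9.33e-15, 0.0323 with estimated correlation). Of 37 members 0 were called by limma, with 0 higher and 19 lower at an unadjusted p under 0.05, and 0 risen and 11 fallen over the list alone. Mitosis genes fell (median −0.73, camera adjusted p = 1.94e-13, 0.111 with estimated correlation). Of 37 members 0 were called by limma, with 0 higher and 14 lower at an unadjusted p under 0.05, and 0 risen and 2 fallen over the list alone. The FGF and ERK feedback list, also holding Ccnd1 and Hmga2, fell (median −0.63, camera adjusted p = 2.47e-09, 0.0236 with estimated correlation). Of 19 members 0 rose, these 2 fell and 17 were not called, with 1 risen and 9 fallen over the list alone. Ribosome biogenesis fell (median −0.33, camera adjusted p = 3.01e-06, 0.18 with estimated correlation). Of 28 members 0 were called by limma, with 0 higher and 7 lower at an unadjusted p under 0.05, and 0 risen and 2 fallen over the list alone. The non-muscle and smooth muscle cytoskeleton fell (median −0.39, camera adjusted p = 0.00115, 0.2 with estimated correlation). Of 25 members 0 were called by limma, with 1 higher and 6 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone.

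The calls for single genes at 6 h depend on single samples. Without the wtp16 sample of 0 h 5 probe sets were called and all 18 of the largest genes lost their call. The rises were then Klhl40 (1.92), Ppfia4 (1.54), Pdlim3 (1.76), Maf (1.92), Fibin (1.32), Slc40a1 (1.34), Msmo1 (1.56), Rbm24 (1.19), Narf (1.25) and Tpd52l1 (1.26), with adjusted p from 0.0887 to 0.354. The falls were Hmga2 (−2.24), Ccnd1 (−1.89), Zfp36l2 (−2.27), Errfi1 (−1.42), Pdpn (−1.31), Rai14 (−1.18), Dok1 (−0.89) and H2ax (−0.82), with adjusted p from 0.0541 to 0.383. Leaving out the 6 h samples of mb1, wtp16 and wt841 gave 98, 16 and 8 called probe sets and ended the calls of 4, 11 and 15 of the 18 genes. Leaving out mb1 of 0 h ended 8, and leaving out wt841 of 0 h ended none and gave 383 called probe sets. Without the culture block 4 probe sets were called, and of the 18 genes only Pdlim3 was left.

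Other settings ended single calls at 6 h. With a pseudocount of 1 they were Ccnd1 (−2.37), Dok1 (−1.15), H2ax (−0.92) and Rai14 (−1.35), with adjusted p from 0.0517 to 0.08. Centring each array on its median ended that of H2ax (−0.86, adjusted p = 0.0676), and scan batch as the block that of Tpd52l1 (1.47, adjusted p = 0.0623). The neuromuscular junction list lost its call without wtp16 of 0 h (0.22, adjusted p = 0.0556) or wt841 of 6 h (0.30, adjusted p = 0.0836). The cytoskeleton list lost it without wt841 of 6 h (−0.30, adjusted p = 0.0551), and cholesterol synthesis without mb1 of 6 h (0.02, adjusted p = 0.211). With the call kept, medians without wtp16 of 0 h were 0.43 (sarcomere), 0.43 (calcium handling), 0.40 (differentiation regulators), 0.10 (respiration) and 0.52 (cholesterol). Without wt841 of 6 h they were 0.59 (calcium handling), 0.32 (energy), −0.41 (mitosis) and 0.53 (cholesterol), and without wt841 of 0 h 1.01 (energy) and −1.03 (FGF and ERK). Without wtp16 of 6 h they were 0.46 (cholesterol) and −0.52 (ribosome biogenesis), and without mb1 of 6 h 0.32 (respiration). The count was 102 with the higher pseudocount, 94 without dim probe sets, 99 with a trended and robust fit and 82 when adjusted within each array type. It was 69 with scan batch as the block and 73 with the wt841 sample of 7 days left out of the fit. A fit with culture and scan batch both as blocks amounts to leaving that sample out. In a fit of the 6 samples alone 0 probe sets were called (limma, 2654 at an unadjusted p under 0.05).

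How far differentiation had gone after 1 day was asked with the 24 h samples against 0 h. Bex1 (log2 change 4.31 ± 0.66 SE, adjusted p = 0.000286, n = 3) rose most, with a mean signal of 9816 ± 2838 against 876 ± 1146. It was followed by Cdkn1c (log2 change 4.15 ± 0.57 SE, adjusted p = 0.000113, n = 3), which encodes an inhibitor of cyclin-dependent kinases, and Myh3 (log2 change 3.97 ± 0.63 SE, adjusted p = 0.000425, n = 3), the embryonic myosin heavy chain. The next were Tm6sf1 (3.91), Unc45b (3.65), Klhl40 (3.60) and Myh1 (3.58), with adjusted p from 2.72e-06 to 0.00294, of which Unc45b is a myosin chaperone and Myh1 a fast myosin heavy chain. After them came Mybph (3.42), Pygm (3.40) and Pgam2 (3.39), with adjusted p from 0.00112 to 0.00383, of which Pygm is the muscle glycogen phosphorylase and Pgam2 the muscle phosphoglycerate mutase. In all 2333 probe sets changed, 1144 higher and 1189 lower, and 2320 of them moved the same way in all 3 cultures. With each array centred on its median 1183 were higher and 1045 lower.

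Pclaf (log2 change −3.94 ± 0.52 SE, adjusted p = 7.38e-05, n = 3) fell most at 24 h, with a mean signal of 263.1 ± 225.4 against 4450 ± 1523. The next falls were those of Ndc80 (−3.76), Cdk1 (−3.71), Top2a (−3.61), Zfp36l2 (−3.56) and Mki67 (−3.54), with adjusted p from 1.16e-05 to 0.00124. Ndc80 belongs to the kinetochore, Cdk1 is the kinase that drives mitosis and Mki67 marks cycling cells. They were followed by Hmga2 (−3.52), Pbk (−3.48), Ccnd1 (−3.48) and Ncapg (−3.46), with adjusted p from 4.43e-05 to 0.000121, of which Ncapg is a condensin subunit. Its signal at 24 h (69.06 ± 40.74) lies below the pseudocount (190.5), and with a pseudocount of 1 its value is −5.37. Mki67 is represented by 1 of 2 probe sets, and its other probe set had a change of −0.10 (adjusted p = 0.951).

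Of the transcription factors, Mef2c (2.82), Myog (2.40), Mef2a (1.46), Myf6 (1.44) and Mef2d (1.03) rose at 24 h, with adjusted p from 0.00215 to 0.0236. Acta1 (2.31, adjusted p = 0.0128) and the cell-cycle inhibitor Cdkn1a (1.52, adjusted p = 0.0193) rose as well. Acta1 stood at 1.82 in mb1, 4.90 in wtp16 and 0.21 in wt841. Myod1 (−0.19, adjusted p = 0.835), Myf5 (−0.35, adjusted p = 0.796) and Ckm (0.13, adjusted p = 0.932) were not called. Of the other probe sets of Ckm 2 rose at 24 h (3.08, adjusted p = 0.00199, and 1.95, adjusted p = 0.0104). Leaving out wtp16 of 0 h ended the calls of Mef2c (1.78), Acta1 (1.13), Cdkn1a (1.26), Mef2d (0.84) and Myf6 (0.92), with adjusted p from 0.0657 to 0.262. Leaving out wtp16 of 24 h ended those of Acta1 (2.05), Mef2c (2.69) and Cdkn1a (1.40), with adjusted p from 0.0638 to 0.103. Those of Mef2c (2.75) and Cdkn1a (1.28) were lost without mb1 of 0 h, with adjusted p from 0.0509 to 0.115, and those of Cdkn1a (1.53) and Myf6 (1.41) without mb1 of 24 h, with adjusted p from 0.0636 to 0.0814. Myf6 was also lost without wt841 of 0 h (1.37, adjusted p = 0.0708) or of 24 h (1.32, adjusted p = 0.1).

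At the level of groups 8 lists rose at 24 h. The sarcomere list rose most (median 2.17, camera adjusted p = 2.29e-22, 0.081 with estimated correlation). Among its 42 members 30 rose, 0 fell and 12 were not called, with 32 risen and 1 fallen over the list alone. Its medians were 1.79 in mb1, 3.15 in wtp16 and 0.92 in wt841. From 0 h to 24 h the ratio of 3' to 5' signal of Actb went from 1.01 to 0.86 in mb1, from 1.12 to 0.90 in wtp16 and from 1.09 to 0.91 in wt841. Excitation-contraction coupling and calcium handling rose (median 1.62, camera adjusted p = 2.55e-12, 0.0808 with estimated correlation). It has 22 members, of which 13 rose, 0 fell and 9 were not called, with 16 risen and 0 fallen over the list alone. Examples are Atp2a1 (3.26), Trdn (3.04) and Cacng1 (2.96), with adjusted p from 4.52e-05 to 0.0012, of which Atp2a1 is the calcium pump of the sarcoplasmic reticulum. Muscle energy metabolism rose (median 1.43, camera adjusted p = 2.5e-09, 0.147 with estimated correlation). Of 28 members 16 rose, 1 fell and 11 were not called, with 18 risen and 1 fallen over the list alone. Beside Pygm and Pgam2 it held Ckb (2.82, adjusted p = 0.00196). Differentiation regulators rose (median 1.38, camera adjusted p = 3.31e-10, 0.0312 with estimated correlation). Among its 22 members 14 rose, 0 fell and 8 were not called, with 16 risen and 0 fallen over the list alone. Among them Smyd1 (2.77, adjusted p = 0.000803) rose beside Cdkn1c.

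Neuromuscular junction genes rose at 24 h (median 0.83, camera adjusted p = 8.36e-07, 0.0236 with estimated correlation). It has 18 members, of which 8 rose, 1 fell and 9 were not called, with 11 risen and 1 fallen over the list alone. The acetylcholine receptor subunits Chrng (2.22) and Chrnd (1.67) rose, as did Erbb3 (2.87) and Sntb1 (1.89), with adjusted p from 6.59e-05 to 0.00061 over the 4. Mitochondrial respiration rose (median 0.45, camera adjusted p = 1.44e-08, 0.166 with estimated correlation). Of 34 members 7 rose, 0 fell and 27 were not called, with 17 risen and 0 fallen over the list alone. Cholesterol synthesis rose (median 0.35, camera adjusted p = 0.000529, 0.22 with estimated correlation). Among its 20 members 6 rose, 0 fell and 14 were not called, with 6 risen and 0 fallen over the list alone. It held Msmo1 (1.76), Fdps (1.64) and Hmgcs1 (1.57), with adjusted p from 0.000451 to 0.00708. Cell-cell fusion and adhesion genes rose (median 0.40, camera adjusted p = 0.0389, 0.18 with estimated correlation). It has 25 members, of which 9 rose, 2 fell and 14 were not called, with 10 risen and 4 fallen over the list alone. They included Itgb1bp2 (3.28), Dysf (3.15) and Mymk (2.90), with adjusted p from 0.000441 to 0.00127, of which Mymk is a membrane protein that fusion requires. The fusion list lost its call without mb1 of 0 h (0.42, adjusted p = 0.0716), wtp16 of 0 h (0.23, adjusted p = 0.0606) or mb1 of 24 h (0.36, adjusted p = 0.094). It was also lost without dim probe sets (0.37, adjusted p = 0.0739), after quantile normalization (0.33, adjusted p = 0.0731) and in the 6 samples alone (0.40, adjusted p = 0.165).

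At 24 h 5 lists fell. Mitosis genes fell furthest (median −2.64, camera adjusted p = 2.76e-44, 0.0112 with estimated correlation). Of 37 members 0 rose, 35 fell and 2 were not called, with 0 risen and 36 fallen over the list alone. Kif23 (−3.34, adjusted p = 0.000271) fell beside Ndc80, Cdk1 and Top2a. DNA replication and G1/S followed (median −1.63, camera adjusted p = 1.99e-24, 0.0112 with estimated correlation). Among its 37 members 0 rose, 27 fell and 10 were not called, with 0 risen and 28 fallen over the list alone. Examples are Uhrf1 (−3.28), Mcm5 (−2.95), Rrm2 (−2.56) and Mcm7 (−2.45), with adjusted p from 3.61e-05 to 0.000911. Ribosome biogenesis fell (median −0.66, camera adjusted p = 6.8e-11, 0.0808 with estimated correlation). It has 28 members, of which 0 rose, 9 fell and 19 were not called, with 0 risen and 19 fallen over the list alone. It held Nop56 (−1.77), Ncl (−1.59), Gar1 (−1.56) and Fbl (−1.45), with adjusted p from 0.000109 to 0.000921. The FGF and ERK feedback list fell (median −1.07, camera adjusted p = 1.94e-06, 0.0628 with estimated correlation). Of 19 members 1 rose, 8 fell and 10 were not called, with 1 risen and 10 fallen over the list alone. Ccnd1 and Hmga2 are in it, but Spry1 (2.62, adjusted p = 0.000338), an inhibitor of that pathway, rose. The non-muscle and smooth muscle cytoskeleton fell (median −0.47, camera adjusted p = 0.00071, 0.185 with estimated correlation). Among its 25 members 2 rose, 7 fell and 16 were not called, with 2 risen and 10 fallen over the list alone. Here Tpm4 (−2.59), Tagln2 (−2.57) and Cald1 (−1.87) fell, with adjusted p from 6.93e-05 to 0.00198, and the smooth muscle actin Acta2 (1.97, adjusted p = 0.00534) rose, but less without wtp16 of 0 h (1.1, adjusted p = 0.0404).

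Of the lists without a call at 24 h, the extracellular matrix and proliferating myoblast regulators had the lowest p-values. The regulators were not called (median −0.19, camera adjusted p = 0.0667). It has 23 members, of which 1 rose, 4 fell and 18 were not called, with 1 risen and 7 fallen over the list alone. Falls were called for Met (−2.47), Id2 (−2.06) and Sdc3 (−1.78), with adjusted p from 0.000156 to 0.000425. The matrix was not called either (median −0.24, camera adjusted p = 0.0549). Of 44 members 1 rose, 7 fell and 36 were not called, with 2 risen and 11 fallen over the list alone. It held Tnc (−3.40, adjusted p = 0.000124). The regulators were called without wt841 of 0 h (−0.26, adjusted p = 0.0424), and the matrix without mb1 of 0 h (−0.33, adjusted p = 0.0352), wtp16 of 24 h (−0.25, adjusted p = 0.00867) or mb1 of 7 days (−0.24, adjusted p = 0.0484).

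Further members that went against a called list at 24 h were chosen after their values were seen. They were Vcam1 (−2.10, adjusted p = 0.000595) and Kirrel (−1.46, adjusted p = 0.00479) of the fusion list and Agrn (−1.22, adjusted p = 0.0237) of the neuromuscular junction. Hk2 (−1.49, adjusted p = 0.0289) of energy metabolism and Vcl (0.88, adjusted p = 0.0205) of the cytoskeleton also belong here. Vcam1 kept its call in every leave-out and without the culture block. Leaving out wtp16 of 0 h ended the calls of Kirrel (−1.21, adjusted p = 0.0608), Agrn (−1, adjusted p = 0.183), Hk2 (−1.53, adjusted p = 0.0965) and Vcl (0.55, adjusted p = 0.24). Agrn was also lost without mb1 of 0 h (−1.26, adjusted p = 0.0605), mb1 of 24 h (−1.09, adjusted p = 0.115) or wt841 of 24 h (−1.09, adjusted p = 0.109). Hk2 was lost without mb1 of 0 h (−1.44, adjusted p = 0.0942), wt841 of 0 h (−1.5, adjusted p = 0.0623) or wtp16 of 24 h (−1.13, adjusted p = 0.225). Vcl was lost without mb1 of 24 h (0.83, adjusted p = 0.0868) or wt841 of 24 h (0.84, adjusted p = 0.0774). With no block the calls of Spry1 (2.62, adjusted p = 0.102), Acta2 (1.97, adjusted p = 0.141) and Kirrel (−1.46, adjusted p = 0.0513) ended. So did those of Agrn (−1.22, adjusted p = 0.239), Hk2 (−1.49, adjusted p = 0.051) and Vcl (0.88, adjusted p = 0.189).

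All 20 of the largest genes kept their call at 24 h whichever sample of 0 h or 24 h was left out, but the count was 1042 without wtp16 of 0 h and 1379 without wtp16 of 24 h. Without wtp16 of 0 h Myh1 (2.24), Mybph (2.27), Pygm (1.97), Mymk (1.89) and Myog (1.44) were smaller by over 1.5 times, with adjusted p from 0.0094 to 0.0271, as were the medians of the sarcomere (1.30) and cytoskeleton (−0.30) lists. A fit without the culture block called 857 probe sets, and Cdkn1c (4.15), Mef2c (2.82), Cdkn1a (1.52), Mef2d (1.03) and Myf6 (1.44) were not among them (adjusted p from 0.0756 to 0.37). In the 6 samples alone 0 probe sets were called (limma, 5476 at an unadjusted p under 0.05).

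**Figure D3:**
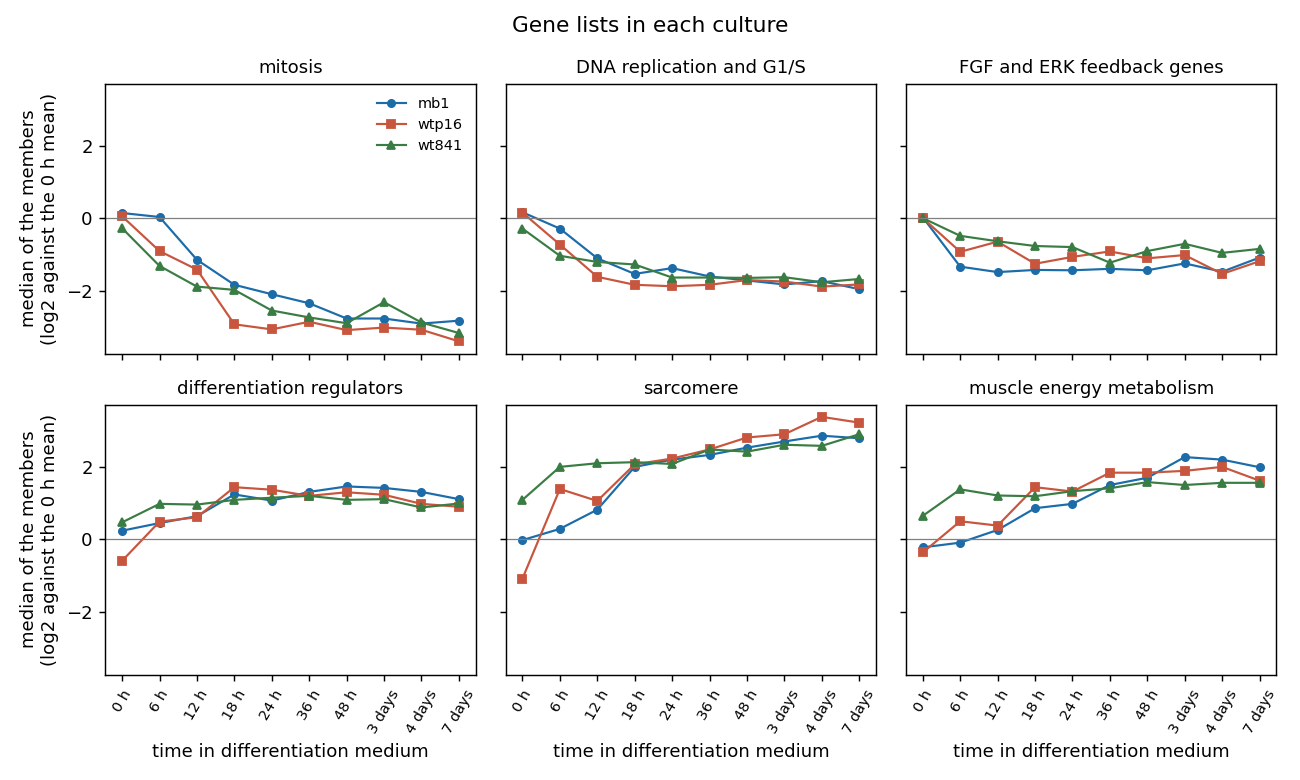
Median log2 difference from the mean at 0 h for 6 gene lists at the 10 times, 1 line per culture.

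The end of the course was read from 7 days against 0 h. Myl2 (log2 change 6.26 ± 0.87 SE, adjusted p = 3.45e-05, n = 3), a regulatory light chain of slow and cardiac muscle, rose most, with a mean signal of 53770 ± 41330 against 683.6 ± 927. Behind it stood Myh4 (6.03), Cox6a2 (5.05), Ankrd23 (4.89), Mybpc1 (4.85) and Coq8a (4.73), with adjusted p from 9.81e-08 to 8.96e-05. Myh4 is a fast myosin heavy chain, Cox6a2 the muscle form of a cytochrome c oxidase subunit and Mybpc1 a myosin-binding protein of slow fibres. The next were Myh1 (4.73), Myh7 (4.64), Tpm3 (4.63) and Scd1 (4.62), with adjusted p from 6.27e-08 to 0.00281, of which Myh7 is the slow myosin heavy chain and Scd1 a fatty acid desaturase. Myh7 is represented by a probe set with a suffix for possible cross-hybridization, and its other probe set fell (−1.31, adjusted p = 0.0359). In all 4802 probe sets changed (13.1%), 2335 higher and 2467 lower, and 4636 moved the same way in all 3 cultures. With each array centred on its median 2572 were higher and 2258 lower.

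Cdk1 (log2 change −5.31 ± 0.51 SE, adjusted p = 6.21e-07, n = 3) fell most by 7 days, with a mean signal of 293.1 ± 182.7 against 15100 ± 9026. It was followed by Kif23 (−4.79), Cdc20 (−4.62), Mki67 (−4.49), Coro1c (−4.36) and Hmga2 (−4.34), with adjusted p from 9.48e-07 to 5.09e-06. Kif23 and Cdc20 act in mitosis. The 7-day signal of Mki67 (24.1 ± 10.23) lies below the pseudocount (79.9), which therefore sets the size and rank of its fall (−6.58 with a pseudocount of 1, −3.06 with the higher one). Single 7-day samples of Kif23, Cpt1a and Top2a lie below it as well. The other falls were those of Cpt1a (−4.24), Rrm2 (−4.24), Top2a (−4.19) and Itgb4 (−4.19), with adjusted p from 9.81e-08 to 2.36e-05, of which Rrm2 is a subunit of ribonucleotide reductase. The other probe set of Mki67 had a change of 0.02 (adjusted p = 0.984).

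The regulators Mef2c (4.23), Myf6 (3.33), Myog (1.65), Mef2a (1.45) and Mef2d (0.93) had risen after 7 days, with adjusted p from 4.5e-06 to 0.0183. Together with them rose Myh3 (4.05), Acta1 (2.91) and Cdkn1a (1.37), with adjusted p from 0.000115 to 0.0221. Myod1 (log2 change −1.29 ± 0.29 SE, adjusted p = 0.0031, n = 3) fell, as did Ccnd1 (−3.67, adjusted p = 4.93e-06). Myf5 (−0.84, adjusted p = 0.266) was not called. Ckm (−0.11, adjusted p = 0.91), the muscle creatine kinase, was not called on the probe set that represents it. Of its other probe sets 2 rose (4.55, adjusted p = 1.49e-05, and 2.90, adjusted p = 0.000122), and the last had −0.13 (adjusted p = 0.859).

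Leaving out wtp16 of 0 h ended the calls of Myog (0.70), Cdkn1a (1.1) and Mef2d (0.74) at 7 days, with adjusted p from 0.0655 to 0.181. Acta1 kept its call without it at a smaller value (1.73, adjusted p = 0.00328), and Myf5 (−1.48, adjusted p = 0.0267) was called without wt841 of 0 h. Myog was also lost without the 7-day sample of wtp16 (1.59, adjusted p = 0.0575) or wt841 (1.41, adjusted p = 0.0884). Cdkn1a was lost without mb1 of 0 h (1.13, adjusted p = 0.118) or of 7 days (1.02, adjusted p = 0.133). With no block Myod1 (−1.29), Myog (1.65), Cdkn1a (1.37) and Mef2d (0.93) were not called (adjusted p from 0.0533 to 0.121).

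By 7 days 8 lists had risen. Of the sarcomere list nearly all members rose (median 3.04, camera adjusted p = 6.23e-28, 0.071 with estimated correlation). Among its 42 members 40 rose, 1 fell and 1 were not called, with 40 risen and 1 fallen over the list alone. Its medians were 2.96 in mb1, 4.21 in wtp16 and 1.63 in wt841. The wt841 sample of 7 days, scanned with wtp16, stands apart from the others of its culture, and the wt841 sample of 0 h held the highest value of the 3 cultures for 34 of the 42 members. Over the same span the ratio of 3' to 5' signal of Actb went from 1.01 to 0.58 in mb1, from 1.12 to 0.57 in wtp16 and from 1.09 to 0.87 in wt841. That of Gapdh stayed between 0.75 and 0.89.

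Excitation-contraction coupling and calcium handling rose by 7 days (median 2.17, camera adjusted p = 5.09e-12, 0.0808 with estimated correlation). It has 22 members, of which 15 rose, 0 fell and 7 were not called, with 18 risen and 0 fallen over the list alone. Examples are Casq1 (4.60), Atp2a1 (4.57), Trdn (4.15) and Ryr1 (3.94), with adjusted p from 2.85e-07 to 0.000361, of which Ryr1 is the calcium release channel. Muscle energy metabolism rose (median 1.5, camera adjusted p = 1.94e-13, 0.0808 with estimated correlation). Of 28 members 18 rose, 0 fell and 10 were not called, with 21 risen and 0 fallen over the list alone. It held Mb (4.28), Pygm (4.22) and Ckmt2 (4.08), with adjusted p from 0.000226 to 0.000622, of which Mb is myoglobin. Mitochondrial respiration rose (median 0.68, camera adjusted p = 7.38e-11, 0.111 with estimated correlation). Among its 34 members 21 rose, 0 fell and 13 were not called, with 25 risen and 0 fallen over the list alone. Subunits of its complexes were Ndufa5 (1.48), Ndufs3 (1.21), Ndufv2 (1.18) and Uqcrc2 (1.16), with adjusted p from 1.79e-05 to 0.000166. Differentiation regulators rose (median 1.15, camera adjusted p = 7.12e-06, 0.0876 with estimated correlation). It has 22 members, of which 12 rose, 0 fell and 10 were not called, with 15 risen and 1 fallen over the list alone. Among them Csrp3 (4.15, adjusted p = 0.000338) rose beside Mef2c and Myf6.

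The neuromuscular junction list rose by 7 days (median 0.83, camera adjusted p = 0.000529, 0.0808 with estimated correlation). Of 18 members 7 rose, 2 fell and 9 were not called, with 10 risen and 2 fallen over the list alone. Chrng (2.39) and Chrnd (2.35) rose, with adjusted p from 1.52e-06 to 7.27e-06. Cholesterol synthesis rose (median 0.75, camera adjusted p = 0.00193, 0.283 with estimated correlation). Among its 20 members 6 rose, 0 fell and 14 were not called, with 10 risen and 0 fallen over the list alone. It held Fdps (2.13), Idi1 (2.05) and Msmo1 (1.64), with adjusted p from 9.59e-06 to 0.00421. FoxO and muscle atrophy genes rose (median 0.35, camera adjusted p = 0.0381, 0.081 with estimated correlation). It has 15 members, of which 4 rose, 1 fell and 10 were not called, with 4 risen and 1 fallen over the list alone. Sesn1 (2.05, adjusted p = 3.22e-05), a stress-induced regulator of growth, rose among them. The FoxO list lost its call without wtp16 of 0 h (0.37, adjusted p = 0.0501), wt841 of 0 h (0.42, adjusted p = 0.0635), wtp16 of 7 days (0.25, adjusted p = 0.0614) or wt841 of 7 days (0.28, adjusted p = 0.0676). It was also lost without dim probe sets (0.29, adjusted p = 0.0839) and with the mean of all probe sets of a gene (0.48, adjusted p = 0.138).

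Another 7 lists fell by 7 days. Mitosis genes fell furthest (median −3.20, camera adjusted p = 3.64e-39, 0.0126 with estimated correlation). Of 37 members 0 rose, 36 fell and 1 were not called, with 0 risen and 36 fallen over the list alone. DNA replication and G1/S followed (median −1.98, camera adjusted p = 2.42e-21, 0.0126 with estimated correlation). Among its 37 members 0 rose, 28 fell and 9 were not called, with 0 risen and 29 fallen over the list alone. It held Uhrf1 (−3.62), Mcm5 (−3.21) and Cdt1 (−3.01) beside Rrm2, with adjusted p from 2.96e-06 to 0.000122. The non-muscle and smooth muscle cytoskeleton fell (median −1.24, camera adjusted p = 1.29e-05, 0.0914 with estimated correlation). It has 25 members, of which 2 rose, 13 fell and 10 were not called, with 3 risen and 14 fallen over the list alone. Tpm4 (−3.67), Tagln2 (−3.32) and Cald1 (−2.81) fell, with adjusted p from 3.78e-07 to 1.11e-05. Proliferating myoblast regulators fell (median −0.63, camera adjusted p = 3.83e-05, 0.0808 with estimated correlation). Of 23 members 0 rose, 8 fell and 15 were not called, with 0 risen and 8 fallen over the list alone. Among them are the inhibitors of myogenic factors Id3 (−4.05), Id2 (−3.63) and Id1 (−3.53) and Met (−2.88), with adjusted p from 3.26e-07 to 0.000196 over the 4.

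The FGF and ERK feedback list fell by 7 days (median −1.40, camera adjusted p = 3.19e-05, 0.0808 with estimated correlation). Of 19 members 1 rose, 10 fell and 8 were not called, with 1 risen and 12 fallen over the list alone. Fosl1 (−3.48, adjusted p = 4.8e-05) fell beside Ccnd1 and Hmga2. Ribosome biogenesis fell (median −0.77, camera adjusted p = 6.46e-10, 0.081 with estimated correlation). It has 28 members, of which 0 rose, 14 fell and 14 were not called, with 0 risen and 18 fallen over the list alone. Examples are Gar1 (−1.90), Nop56 (−1.83) and Rcl1 (−1.71), with adjusted p from 4.88e-06 to 0.00015. Extracellular matrix genes fell (median −0.53, camera adjusted p = 0.000161, 0.0312 with estimated correlation). Of 44 members 1 rose, 15 fell and 28 were not called, with 4 risen and 21 fallen over the list alone. The collagens Col18a1 (−3.41), Col4a1 (−2.62) and Col5a2 (−2.61) and Tnc (−2.59) fell, with adjusted p from 6.96e-07 to 0.000555 over the 4.

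Some members went against their called list at 7 days, all of them chosen after their values were seen. In the falling lists, Spry1 (2.54, adjusted p = 0.00015), S100a4 (1.63, adjusted p = 0.000231), Flna (1.22, adjusted p = 0.0263) and the laminin gene Lama2 (0.94, adjusted p = 0.000981) rose. In the rising lists, Ncam1 (−1.78, adjusted p = 0.00272) and Agrn (−1.42, adjusted p = 0.00418) of the neuromuscular junction, Nebl (−1.32, adjusted p = 0.0376) of the sarcomere and Cited2 (−0.86, adjusted p = 0.0352) of the FoxO list fell. The call of Nebl was lost without mb1 (−1.28, adjusted p = 0.102), wtp16 (−1.38, adjusted p = 0.0875) or wt841 (−1.32, adjusted p = 0.0831) of 0 h. It was also lost without mb1 (−1.12, adjusted p = 0.138) or wtp16 (−0.94, adjusted p = 0.202) of 7 days. Cited2 lost its call without mb1 of 0 h (−0.59, adjusted p = 0.222) or without mb1 (−0.91, adjusted p = 0.0594), wtp16 (−0.88, adjusted p = 0.0718) or wt841 (−0.80, adjusted p = 0.0993) of 7 days. Flna lost its call without wtp16 (1.12, adjusted p = 0.112) or wt841 (1.19, adjusted p = 0.0684) of 0 h and without wtp16 (1.2, adjusted p = 0.0673) or wt841 (0.94, adjusted p = 0.14) of 7 days. With no block the calls of Spry1 (2.54, adjusted p = 0.0676), S100a4 (1.63, adjusted p = 0.333) and Flna (1.22, adjusted p = 0.125) ended. So did those of Agrn (−1.42, adjusted p = 0.0724), Nebl (−1.32, adjusted p = 0.0868) and Cited2 (−0.86, adjusted p = 0.54).

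Lists without a call at 7 days held single changes. Cell-cell fusion and adhesion genes were not called (median −0.14, camera adjusted p = 0.963). Among its 25 members 6 rose, 5 fell and 14 were not called, with 6 risen and 5 fallen over the list alone. Cav3 (3.88), Dysf (3.11) and Itgb1bp2 (2.85) rose and Vcam1 (−2.95) fell, with adjusted p from 5.3e-06 to 0.001, and the mean of that list (0.16) differs in sign from its median and from the direction of the test. TGF-beta and BMP response genes were not called (median −0.44, camera adjusted p = 0.182). It has 20 members, of which 2 rose, 4 fell and 14 were not called, with 2 risen and 7 fallen over the list alone. They held Smad7 (−2.25, adjusted p = 0.000151) and Fst (3.29, adjusted p = 0.00443), which was smaller without wtp16 of 0 h (1.58, adjusted p = 0.00974). The unfolded protein response was not called (median −0.28, camera adjusted p = 0.0716). Of 22 members 1 rose, 5 fell and 16 were not called, with 1 risen and 8 fallen over the list alone. It held Herpud1 (1.42, adjusted p = 0.000938) and was called without wtp16 of 0 h (−0.48, adjusted p = 0.0329) or wt841 of 7 days (−0.42, adjusted p = 0.011). The p53 targets were not called (median −0.22, camera adjusted p = 0.869). Among its 17 members 3 rose, 2 fell and 12 were not called, with 3 risen and 3 fallen over the list alone. They held Zmat3 (−1.54, adjusted p = 4.55e-05) and Sesn1. The IGF axis was not called (median −0.11, camera adjusted p = 0.995). It has 12 members, of which 2 rose, 1 fell and 9 were not called, with 2 risen and 2 fallen over the list alone. It held Igfbp6 (2.42, adjusted p = 0.000218).

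Immediate early genes were not called at 7 days (median 0.11, camera adjusted p = 0.674). Of 20 members 1 rose, 0 fell and 19 were not called, with 1 risen and 0 fallen over the list alone. The proteasome was not called (median 0.00, camera adjusted p = 0.755). Among its 27 members 2 rose, 0 fell and 25 were not called, with 0 risen and 0 fallen over the list alone. The interferon response was not called (median 0.02, camera adjusted p = 0.817). Of 26 members 0 were called by limma, with 1 higher and 2 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone.

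Markers of cells other than muscle gave no list call in any of the 4 comparisons. Fibroblast markers at 7 days against 0 h were at this level (median −0.08, camera adjusted p = 0.182). Of 15 members 0 rose, 4 fell and 11 were not called, with 1 risen and 5 fallen over the list alone. Serpinf1 (−3.04) and Col3a1 (−2.10) fell, with adjusted p from 0.00021 to 0.000708. Smooth muscle and pericyte markers showed changes both ways (median −0.14, camera adjusted p = 0.413). Among its 12 members 1 rose, 4 fell and 7 were not called, with 2 risen and 4 fallen over the list alone. Endothelial markers were not called (median 0.11, camera adjusted p = 0.932). It has 13 members, of which 1 rose, 2 fell and 10 were not called, with 1 risen and 2 fallen over the list alone. Macrophage and leukocyte markers held Laptm5 (−1.61, adjusted p = 0.000585) as their single fall (median 0.02, camera adjusted p = 0.951). Of 17 members 0 rose, 1 fell and 16 were not called, with 0 risen and 1 fallen over the list alone. Adipocyte markers were not called (median 0.00, camera adjusted p = 0.932). Of 10 members 0 were called by limma, with 0 higher and 0 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone. Schwann cell markers were not called (median −0.07, camera adjusted p = 1). Of 7 members 0 were called by limma, with 0 higher and 0 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone. Bone and cartilage markers were not called (median −0.06, camera adjusted p = 0.932). Of 8 members 0 were called by limma, with 0 higher and 0 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone.

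The 20 largest genes of 7 days kept their call whichever sample was left out, and the count was 3049 without wtp16 of 0 h. Without it Myh7 (2.81), Csrp3 (2.75) and Pygm (2.79) were smaller by over 1.5 times, with adjusted p from 0.000675 to 0.0333, as was the median of the differentiation regulators (0.75), while that of the proliferating myoblast regulators was −0.97 without wt841 of 0 h. With the wt841 sample of 7 days left out 4574 probe sets were called, 3637 of them among the 4802 and in the same direction. A fit without the culture block called 2149. In the 6 samples alone 830 were called, which left out Myh1, Myh7, Myh3, Acta1, Cdkn1a, Mef2a, Mef2d, Myod1 and Myog and 47 of the 93 list members that the rule names.

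Later change was read from 7 days against 48 h, where 3 probe sets were called (limma, n = 3, 3324 at an unadjusted p under 0.05). Mapt, which encodes the microtubule protein tau, rose (3.44 ± 0.48 SE, adjusted p = 0.013), with a mean signal of 2550 ± 1145 against 155.1 ± 81.84. Vasp (−1.5 ± 0.23 SE, adjusted p = 0.0149), an actin filament regulator, fell, with 3757 ± 1899 against 11430 ± 6079. Plagl1, a zinc finger transcription factor, fell too (−2.41 ± 0.38 SE, adjusted p = 0.0149), with 1868 ± 2612 against 7617 ± 5829. Mapt and Plagl1 lie outside the naming rule and were chosen after their values were seen. None of the fixed genes was called, Myf6 (1.53, adjusted p = 0.2) being largest. Next were Mef2c (0.69), Myod1 (−0.51), Ckm (0.46), Acta1 (0.45), Myog (−0.32) and Mef2d (−0.31), with adjusted p from 0.625 to 0.885. The others were Myf5 (−0.24), Mki67 (−0.21), Cdkn1a (−0.19), Myh3 (−0.18), Ccnd1 (−0.17) and Mef2a (−0.02), with adjusted p from 0.922 to 0.992.

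Between 48 h and 7 days 5 lists passed the threshold. FoxO and muscle atrophy genes rose (median 0.41, camera adjusted p = 6.88e-05, 0.0112 with estimated correlation). Of 15 members 0 were called by limma, with 4 higher and 0 lower at an unadjusted p under 0.05, and 2 risen and 0 fallen over the list alone. The sarcomere list rose (median 0.36, camera adjusted p = 0.00182, 0.634 with estimated correlation). Of 42 members 0 were called by limma, with 6 higher and 0 lower at an unadjusted p under 0.05, and 4 risen and 0 fallen over the list alone. Muscle energy metabolism rose (median 0.32, camera adjusted p = 0.0444, 0.664 with estimated correlation). Of 28 members 0 were called by limma, with 2 higher and 1 lower at an unadjusted p under 0.05, and 0 risen and 0 fallen over the list alone. Cell-cell fusion and adhesion genes fell (median −0.37, camera adjusted p = 0.000564, 0.0596 with estimated correlation). Of 25 members 0 were called by limma, with 0 higher and 5 lower at an unadjusted p under 0.05, and 0 risen and 4 fallen over the list alone. The extracellular matrix fell (median −0.24, camera adjusted p = 0.00134, 0.0628 with estimated correlation). Of 44 members 0 were called by limma, with 0 higher and 4 lower at an unadjusted p under 0.05, and 0 risen and 3 fallen over the list alone. Its medians were 0.01 in mb1, −0.25 in wtp16 and −0.61 in wt841.

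Most calls of the late comparison depend on single samples, and only the FoxO and fusion lists kept theirs in every leave-out. Without wt841 of 48 h the sarcomere list (0.07, adjusted p = 0.217) and the energy list (0.16, adjusted p = 0.394) lost their calls. Without mb1 of 7 days the energy list (0.00, adjusted p = 0.928) lost it, and without wt841 of 7 days the matrix list (−0.05, adjusted p = 0.186). The matrix list was also lost with scan batch as the block (−0.07, adjusted p = 0.212). The energy list was also lost with the mean of all probe sets (0.21, adjusted p = 0.0666), a pseudocount of 1 (0.32, adjusted p = 0.0642) and quantile normalization (0.15, adjusted p = 0.131).

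Vasp was lost without mb1 of 48 h (−1.45, adjusted p = 0.14), wt841 of 48 h (−1.41, adjusted p = 0.139) or wt841 of 7 days (−1.24, adjusted p = 0.0566). It was also lost with scan batch as the block (−1.09, adjusted p = 0.0683), a pseudocount of 1 (−1.53, adjusted p = 0.0608), no block (−1.5, adjusted p = 1) and the 6 samples alone (−1.5, adjusted p = 0.87). Plagl1 was lost without mb1 of 48 h (−2.45, adjusted p = 0.131), wt841 of 48 h (−2.20, adjusted p = 0.14), wtp16 of 7 days (−2.41, adjusted p = 0.055) or wt841 of 7 days (−1.91, adjusted p = 0.0656) and with no block (−2.41, adjusted p = 1). Mapt was lost without mb1 of 48 h (3.34, adjusted p = 0.131) or wt841 of 48 h (3.50, adjusted p = 0.0532) and with no block (3.44, adjusted p = 0.165). The count was 0 without mb1 of 48 h (limma, 3003 at an unadjusted p under 0.05), 1 without wt841 of 48 h, 50 without mb1 of 7 days and 5 without wtp16 of 7 days. It was 0 with no block (1562 unadjusted), 0 with a pseudocount of 1 (3145 unadjusted) and 0 in the 6 samples alone (2057 unadjusted). It was 16 with the higher pseudocount, 9 with scan batch as the block, 6 after quantile normalization and 5 after median centring.

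How much the 3 cultures differ at the same time was asked over all 10 times. Pdxdc1 had the largest range, with a mean signal of 81.33 ± 56.74 in mb1, 8726 ± 2068 in wtp16 and 8801 ± 555.7 in wt841 (range 5.85 log2, adjusted p = 3.81e-18, n = 10 times per culture). Its mb1 signal stands at the pseudocount (79.9), which therefore sets the size and rank of that range, 7.00 with a pseudocount of 1 and 4.66 with the higher one, where Tusc1 leads (4.83). Tusc1 (4.92), Ccn2 (4.10), Jun (4.05) and Ankrd2 (3.94) were likewise lowest in mb1 and were highest in wtp16, with adjusted p from 6.95e-14 to 7.33e-08. Car3 (4.29, adjusted p = 2.39e-08) and Fbln2 (3.93, adjusted p = 1.94e-11) were highest in wt841, and Rpgrip1 (4.25, adjusted p = 6.06e-13) was highest in mb1. Lmcd1 (4.42, adjusted p = 1.44e-10) and Myh4 (4.04, adjusted p = 1.48e-06), the fast myosin heavy chain, were lowest in wtp16 and, on the log scale, highest in wt841. Myh4 had 13980 ± 26390 in mb1, 1231 ± 1711 in wtp16 and 12290 ± 11080 in wt841. In all 18817 of the 36701 probe sets (51.3%) differed between cultures. The 10 values of a culture are times of 1 series, so their SD holds the change over time and the p-values here use times, not cultures, as replicates.

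Of the fixed genes, Myf5 had the largest range between cultures (2.14, adjusted p = 1.8e-06), with 788.5 ± 623.6 in mb1, 3862 ± 3148 in wtp16 and 1889 ± 559 in wt841. Mef2c (1.34), Myf6 (1.33), Myh3 (1.27), Ccnd1 (1.07) and Myod1 (0.98) differed less, with adjusted p from 8.62e-05 to 0.0161. Ckm (0.84), Cdkn1a (0.65), Mef2d (0.49) and Mef2a (0.47) had adjusted p from 0.00482 to 0.0485. Mki67 (0.63, adjusted p = 0.156), Myog (0.56, adjusted p = 0.134) and Acta1 (0.46, adjusted p = 0.364) were not called. Each culture was scanned as its own batch, apart from the wt841 sample of 7 days, so that a difference of mb1 from the others cannot be told from a difference between scans. The wt841 and wtp16 cultures share a batch only at 7 days, with n = 1 each, where wt841 minus wtp16 was 3.33 for Lmcd1, 3.10 for Myh4, 2.87 for Fbln2 and 2.20 for Car3, and between −0.81 (Ankrd2) and 0.58 (Ccn2) for the other 6 of the 10 genes. The count was 5114 without wtp16 and 12042 without mb1.

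**Figure D4:**
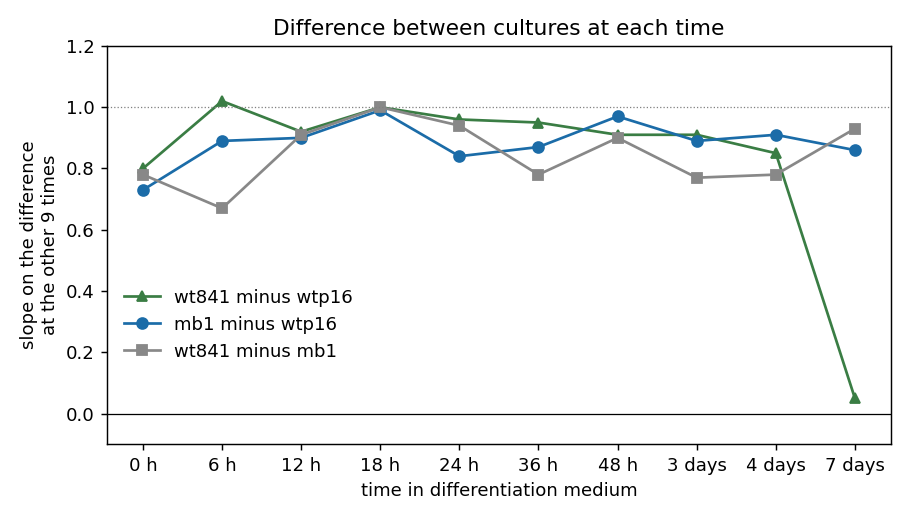
Slope of the difference between 2 cultures at each time on their difference at the other 9 times.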

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

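The test of culture by phase and the tests of the 3 patterns weighed here were chosen only after the data were seen. A test of whether cultures change differently between an early phase (0 to 18 h, n = 4 times) and a late phase (24 h to 7 days, n = 6 times) called 59 of 36701 probe sets in limma, and 1 of 100 regroupings that deal the times to the phases alike in all cultures, the real one, called as many (highest other 54). The times of a culture are 1 ordered series and the phases were chosen with the data in view, so this does not settle the part of chance. Times shuffled separately in each culture, tried first, gave a highest other of 3, but that puts the shared change over time into the residual and was set aside. Of the genes named by the rule, Id3, an inhibitor of myogenic factors, was singled out by this test (adjusted p = 0.0184), with late minus early values of −3.53 in mb1, −3.11 in wtp16 and −1.20 in wt841. Rgs5, a pericyte marker, was singled out as well (adjusted p = 0.0354), with −1.38, −2.30 and −0.09. The count was 100 after quantile normalization, 19 with a pseudocount of 1, 231 with the higher pseudocount, 202 without dim probe sets, 255 with a trended and robust fit, 165 when adjusted within each array type, and 0, 1 and 0 without mb1, wtp16 and wt841. The adjustment allows about 1 in 20 false calls, and groups of 3 samples were not searched for outlying samples.

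The wt841 and wtp16 cultures differ from 0 h to 4 days and hardly at 7 days. The slope of their 7-day difference on their difference at the other 9 times is 0.05 (14190 probe sets, 49.3% with the same sign), against 0.80 to 1.02 at the other times and 0.86 for mb1 against wtp16 at 7 days, as a scan batch would give, since the 7-day sample of wt841 was scanned with wtp16. That this sample is a wtp16 sample under a wrong label is argued against by 135 probe sets that mark wt841 off from both other cultures: at 7 days they keep a median share of 0.66 of the wt841 excess (quartiles 0.22 to 1.08), and 116 of them (85.9%) are higher in wt841. Gradual convergence is argued against by the slope of 0.85 at 4 days, which is not below the lowest of 0 h to 48 h (0.80). A difference between scans may make up much of the culture differences, but a convergence after 4 days is not excluded. How much of the differences is biological stays open and untested.

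Muscle genes are already high in wt841 at 0 h, where the sarcomere medians stand at −0.02 in mb1, −1.08 in wtp16 and 1.09 in wt841. A 0 h sample taken at a later time is argued against by the mitosis members, of which 100% have their highest wt841 signal at 0 h (67.6% in mb1 and 97.3% in wtp16), and a constant offset of the scan batch by the rise to 24 h, which falls short in wt841 by a median of −1.73 (quartiles −2.78 to −0.86). Compressed fold changes are argued against for the 26 sarcomere members within the signal range of the mitosis members, which keep 50.9% of the change seen in the other cultures where the mitosis members keep 83.7% (quartiles 73.2 to 92.2). For the 16 brighter members, which keep 26.7%, compression stays open, because the 56 falling probe sets above that range keep 64.7% but are less bright (median highest log2 signal 15.26 against 16.36). Of the differentiation regulators, 54.5% (12 of 22) rise less in wt841 than in both other cultures, so that an early start of differentiation in part of this culture may play a role beside compression of bright signals, a hypothesis found and tested on the same 3 cultures.

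The count at 7 days is the highest of the course, 4802 against 4202 at 4 days. Without the 7-day sample of wt841 alone it is 4574, from 2 cultures, and below the 4665 at 4 days, from 3. With wt841 left out at both times, so that each holds 2 cultures, it is 4553 against 4391, a ratio of 1.04, where all samples give 1.14 and leaving out mb1 or wtp16 in the same way gives 1.42 or 1.43. How much of the last step comes from the 7-day sample of wt841 and its scan batch stays open, because a count has no spread to judge the ratio by. No biological explanation was tested for it.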

How the results depend on the processing

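The alternatives with both blocks, with scan batch as a further block and with the doubted sample left out were chosen after seeing the data, and no called list and no called gene of the naming rule changed its direction under the alternatives run for it. The balance of higher to lower calls did turn under several settings, for example at 6 h from 28 and 16 to 45 and 57 with a pseudocount at the 40th percentile, at 24 h from 1144 and 1189 to 1183 and 1045 after centring each array on its median, and at 7 days from 2335 and 2467 to 2572 and 2258 after that centring. With an estimated correlation the list calls turned from 26 up and 19 down to 3 and 7. Of the single genes named, 1340 of 1584 leave-out results stayed on their side of the threshold, 9 passed it and 235 fell short of it, and for lists it was 1764 of 1800, with 21 and 15. At 7 days against 48 h (3 probe sets) the count was 6 after quantile normalization, 5 after centring each array on its median, 0 with a pseudocount of 1 (limma, 3145 at an unadjusted p under 0.05), 16 with a pseudocount at the 40th percentile and 9 with scan batch as the block. At 6 h (44 probe sets) it was 102 with that higher pseudocount, 94 without dim probe sets, 99 with a trended and robust fit, 82 when adjusted within each array type, 69 with scan batch as the block and 73 with culture and scan batch both as blocks, which amounts to leaving the doubted sample out (73). A pseudocount of 1 gave 305 at 12 h. The cause was not tested. Without the culture block, which pairs the samples, the counts from 6 h to 7 days were 4, 59, 653, 857, 1170, 1370, 1706, 1928 and 2149, with 0 at 7 days against 48 h (1562 unadjusted) and 1096 over the course, because differences between cultures then count as noise. Lists called without it stayed as they were in 119 of 120 tests. With scan batch as a further block the culture count was 71 (3875 unadjusted), a contrast of wt841 against wtp16 alone that rests on 1 wt841 sample, that of 7 days, and therefore says nothing about the calls over 3 cultures. In fits of only 6 samples, which have fewer samples to estimate the spread from, the counts were 0 at 6 h, 12 h, 18 h, 24 h and 36 h (limma, 2654, 3824, 4857, 5476 and 5603 unadjusted), 193 at 48 h, 287 at 3 days, 341 at 4 days, 830 at 7 days and 0 at 7 days against 48 h (2057 unadjusted). With an estimated correlation 10 of the 45 list calls were left. Leaving out 1 compared sample gave 5 to 383 at 6 h, 55 to 1004 at 12 h and 723 to 2274 at 18 h. It gave 1042 to 2475 at 24 h, 1527 to 3048 at 36 h and 1857 to 3457 at 48 h. It gave 2341 to 3994 at 3 days, 2633 to 4148 at 4 days and 3049 to 4574 at 7 days. At 7 days against 48 h it gave 0 to 50 (3003 unadjusted at the lowest), and for lists 43 to 47. Each lowest against 0 h came without wtp16 of 0 h. Leaving out a culture gave 245 to 2068 for the course and 5114 to 15526 for the culture difference. A group with fewer samples is assumed to vary like the others. The other 2 scalings moved the median of all probe sets by −0.03 to 0.07 log2. What signal over background limits was examined only through the pseudocount and by leaving dim probe sets out, as given above, since the simulated values were not split by brightness.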

Other observations

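The gene groups between the tested times were described by their medians alone, and the splits and regroupings below were planned before the data were examined, except that the phase comparison and its regrouping were chosen after. Sarcomere genes stood at a median log2 difference from 0 h of 1.47 at 12 h, 2.05 at 18 h, 2.39 at 36 h, 2.63 at 48 h, 2.81 at 3 days and 2.90 at 4 days. Mitosis genes stood at −1.53, −2.22, −2.68, −3.06, −2.73 and −3.09 at the same times, and DNA replication and G1/S genes at −1.24, −1.51, −1.82, −1.80, −1.76 and −1.72. The non-muscle and smooth muscle cytoskeleton stood at −0.47, −0.40, −0.73, −0.90, −1.09 and −1.11. Differentiation regulators had their highest median at 18 h (1.48).

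Each comparison of 3 samples against 3 allows 10 splits, which are too few for a share under 0.05, and 4 of them, the real one included, keep the pairing by culture, with a sample of each culture on either side. At 6 h 2 splits gave as many calls as the real one (44, highest other 219), the other with both mb1 samples and wtp16 of 0 h against the rest. Culture is blocked, so a constant offset of culture or scan batch does not give the 219. That side has 46.7 to 79.2 on principal component 2 of array A, which falls with time, and the rest 9 to 40.9. On array C the sides overlap. Why the split calls more was not tested. It breaks the pairing, and among the splits that keep it the highest other count at 6 h was 1. At 12 h 1 split, the real one, gave as many (557, highest other 1), as at 18 h (1 split, 2037 and 1), 24 h (1 split, 2333 and 1), 36 h (1 split, 2913 and 0), 48 h (1 split, 3341 and 0), 3 days (1 split, 3983 and 0), 4 days (1 split, 4202 and 1) and 7 days (1 split, 4802 and 14). At 7 days against 48 h 2 splits gave as many (3, highest other 5), the other one with both mb1 samples and the wt841 sample of 48 h against the rest, and the highest other count among the splits that keep the pairing was 2. Of 100 regroupings 1 was as large for the time course (3382, highest other 480) and 1 for the culture difference (18817, highest other 2). Both shufflings treat the 10 times of a culture as independent, although they are 1 series mostly in 1 scan batch. Shuffling times within each culture also puts shared change into the residual. The preset bound was therefore wrong for this design, and these counts say nothing about chance. For the 45 list calls 5 of 100 regroupings gave as many (highest other 48, median 23), so that chance is not excluded for their number.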
